A study of Mus musculus with 2 samples.

How the data were processed

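The data are droplet-based single-cell RNA counts (10x Genomics) from the injured tendon area of mice, 1 library for TrkA WT and 1 for TrkA F592A, each from a pool of 3 mice per the study design in the labels. Per the labels' protocols, tissue was digested with collagenase and dispase, filtered and loaded as live single cells, and libraries were sequenced on a NovaSeq instrument. The counts were made by the authors before they were deposited: per the file headers, reads were counted with Cell Ranger 6.0.1, while the submitters' processing notes name Cell Ranger 2.1.1, Seurat and mm10. Which version applies is not given in the sources used here. The deposited matrices held whole UMI counts for 32285 features, and every barcode had at least 500 UMIs, so barcodes had been chosen upstream. No FASTQ reads were used here. Whether the WT mice also received the inhibitor, its dose and its schedule are not given in the sources used here.

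A barcode was kept as a cell with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which 11599 WT and 8664 F592A barcodes passed. Scrublet was run on each library and called 342 WT (2.95%) and 220 F592A (2.54%) doublets, which were left out. The remaining 11257 WT and 8444 F592A cells held 205440446 and 170375806 UMIs, a median of 3612 and 3638 genes and a median mitochondrial share of 4.62% and 3.80%. Each cell was scaled to a total of 10000 and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 gave 23 clusters, with both libraries together and no integration. Clusters were assigned to classes by marker lists fixed before the data were examined. Clusters 3, 5, 8, 13, 14, 16, 18 and 20 formed the stromal class, clusters 0, 9 and 17 the macrophage class, cluster 2 the endothelial class and clusters 15, 19 and 21 the mural class. Clusters 6 and 7 were neutrophils, 11 lymphatic endothelium, 12 dendritic cells with a small part of plasma cells, 22 T or NK cells, and clusters 1 and 10 carried markers of several types and stayed unnamed. Cluster 4 had high mesenchymal markers but also Acan and Sox9 among its 10 leading genes and was kept apart. Cluster sizes were not compared where the leading genes differed between libraries inside the cluster by a median of 0.50 or more, taken at 2 decimals, on the log2 scale (clusters 1, 7, 10, 18 and 20, with cluster 18 at the limit), a limit chosen after seeing the data.

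Shares of cells carry exact binomial 95% intervals, and ratios of shares carry 95% intervals by the Katz log method. UMIs were summed per class and library and given as CPM of the class total with exact Poisson 95% intervals, and log2 ratios carry exact conditional binomial intervals. A gene was measured with at least 100 UMIs over both libraries, which held for 13535 genes in stromal cells, 10025 in macrophages and 8978 in endothelial cells. A rule of size counted genes at least 2-fold apart with at least 20 CPM in the higher library. Named genes were the 10 highest and 10 lowest in stromal cells and the 5 highest and 5 lowest in the other classes by that rule, and 1 endothelial gene picked so is not reported here. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes were left out of naming. So were names of the form Gm plus digits, ending in Rik or starting with AC or AL plus digits. Together these were 174, 167 and 176 genes in stromal, macrophage and endothelial cells. Genes whose CPM in the class was below 1/4 of that in the highest class were also left out of naming (393, 369 and 442 genes), as their UMIs may come from other cells. Gene coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10.

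The 32 gene lists covered TGF-beta ligands, receptors and Smads, TGF-beta response, collagens and fibrous matrix, collagen processing, tendon differentiation, chondrogenic, osteogenic, myofibroblast contractile, matrix proteases and inhibitors, neurotrophins and receptors, axon guidance, neuropeptide receptors, angiogenic factors, hypoxia and glycolysis, and oxidative phosphorylation genes. They also covered inflammatory cytokines and chemokines, interferon response, MHC class II, resident and alternatively activated macrophage, lipid-associated macrophage, phagocyte receptors and complement, cell cycle, immediate early and dissociation, BMP and GDF, Wnt, Hedgehog, IGF with FGF and PDGF, senescence and p53, endothelial identity and sprouting, leukocyte adhesion, haemoglobin, and sex-linked genes. For each list with at least 4 measured members, the median log2 ratio minus the median of all measured genes of the class was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. Cycling cells were cells with at least 2 UMIs on the cell cycle list after thinning each cell to 2000 UMIs, and shallower cells were left out of that share. Neutrophil cluster 6 gave the background. Cluster 7 was left out of it after the data were seen, as its leading genes (Ngp, Camp, Ltf) are those of immature neutrophils and 37 of its 70 cells had barcodes found in both libraries.

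Alternatives fixed with the design were stricter cell filters, every barcode, doublets kept, Leiden resolution 0.4 and 1.2, components centred per library, immune or non-immune cells as denominator, TMM and median-of-ratios factors, totals without mitochondrial and ribosomal protein genes, means of per-cell CPM, thinned cells, clusters weighted equally, other count minima, and other settings for cycling cells. Chosen after seeing the data were leaving out barcodes found in both libraries, adding cluster 4 to the stromal class, leaving out clusters 13, 20 or 5 and 18, and cluster 3 alone. In a self-test on simulated Poisson sums at the levels and depths of each class, with 200 genes altered by a known fold, the rule of size found 100% of the 4-fold genes and 0% of the 1.5-fold genes in each class. It called 0 of 5125, 0 of 4824 and 0 of 5397 unaltered genes in stromal, macrophage and endothelial cells, and the counting intervals held the true value for 94.7%, 94.8% and 95.6% of genes. Lists altered by 1.5-fold lay above every random list, and unaltered lists lay at percentiles of 57.0, 28.9 and 30.8. The simulated sums varied by counting alone, with no difference between pools or cluster mixtures. The self-test therefore gives no rate of false calls for the real libraries. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only. No test between groups was run, as each group is 1 library. RNA velocity, inferred trajectories and cell communication scores were not run.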

Results

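Single cells from the injured tendon area of mice were profiled 14 days after tendon injury with droplet capture and counting of unique molecular identifiers (UMIs, tags that mark single captured RNA molecules). The animals were 12 weeks old, and 3 mice were pooled for each genotype, giving 1 library of TrkA WT mice and 1 library of TrkA F592A mice. TrkA is a receptor tyrosine kinase of the neurotrophin family. The F592A point mutation lets a bulky kinase inhibitor block the enzyme, and the title of the F592A sample names such an inhibitor. The comparison therefore asks how cells of the healing tendon differ between WT and F592A mice in which TrkA kinase activity was to be blocked. Whether the WT mice received the inhibitor is not given. Effects of blocked TrkA, of the mutation itself and of the inhibitor on other targets can therefore not be told apart. The WT library held 14868 barcodes with 222874195 UMIs, and the F592A library held 10677 barcodes with 181472230 UMIs. After filtering, 11257 WT cells and 8444 F592A cells remained, with a median of 15870 and 17886.5 UMIs per cell. There were no replicate libraries, so no difference has a replicate check and none was tested. All intervals are 95% intervals that cover counting error only, and "higher" and "lower" describe the F592A library against the WT library.

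Of the neurotrophin receptor genes, Ngfr, Ntrk2 and Ntrk3 had their highest level in mural cells, the contractile cells around vessels, among the classes compared. The genotype labels were not checked, as a point mutation need not alter a transcript level. Ngfr, the low-affinity neurotrophin receptor, was 35.9 CPM (UMIs scaled to a common total) in WT and 40.7 CPM in F592A mural cells, and its log2 ratio of 0.18 had an interval from -0.06 to 0.43. Ntrk2 and Ntrk3 were higher in F592A. Ntrk2, the receptor for brain-derived neurotrophic factor, was 84.2 and 144.5 CPM in mural cells (log2 ratio 0.78) and 5.03 and 12.8 CPM in stromal cells (log2 ratio 1.35, interval 1.21 to 1.49). Inside stromal clusters it was 2.25 in cluster 3 (19 and 90 UMIs), 0.98 in 5, 0.91 in 8 and 0.93 in 16. Its interval included 0 in clusters 13 (-0.81), 14 (0.41) and 18 (-0.08). Ntrk2 was also higher in macrophages (10 and 23 UMIs) and endothelial cells (4 and 32 UMIs), but lower in unnamed cells (15 and 3 UMIs). Free RNA of mural cells was not separated from a stromal difference. Mural Ntrk3, the receptor for neurotrophin-3, rested on 27 WT and 126 F592A UMIs, with a log2 ratio of 2.02 (interval 1.41 to 2.67). The mural class mixed its clusters in different proportions, with 31 WT and 99 F592A cells in cluster 21 and 548 and 494 in cluster 15.

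The stromal class took nearly equal shares of both libraries, 45.4% of WT cells (interval 44.5 to 46.3) and 45.9% of F592A cells (interval 44.8 to 46.9). Vessel cells were a larger part of the F592A library. The endothelial share was 5.35% in WT (interval 4.94 to 5.78) and 7.69% in F592A (interval 7.13 to 8.27), a ratio of 1.44 (interval 1.29 to 1.60), and the mural share was 5.52% and 7.30%, a ratio of 1.32 (interval 1.19 to 1.47). T or NK cells made up 0.951% and 1.80%, a ratio of 1.89 (interval 1.48 to 2.42). Macrophages were a smaller part of F592A, with 22.6% in WT (interval 21.8 to 23.4) and 20.1% in F592A (interval 19.2 to 20.97), a ratio of 0.890. The intervals of the ratio included 1 for neutrophils (2.44% and 2.08%), dendritic cells (1.46% and 1.65%) and lymphatic endothelial cells (0.942% and 1.13%). The neutrophil class included cluster 7, whose size was not compared. Neutrophil cluster 6 alone held 2.17% and 1.62%, a ratio of 0.749 (interval 0.608 to 0.921). Cluster 4, led by Rbp4, Wfdc18, Cyp26b1 and the cartilage genes Acan and Sox9, was kept out of the stromal class. It held 12.0% of WT cells (interval 11.4 to 12.6) and 8.59% of F592A cells (interval 7.997 to 9.20), a ratio of 0.715 (interval 0.657 to 0.779). Each share is bound to the tissue dissected and to how well each cell type survived enzymatic dissociation.

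Within the stromal class, the mixture of clusters differed more than the class total. Cluster 5, led by Cd55, Efemp1, Prss23 and Cd248, held 7.20% of WT cells (interval 6.73 to 7.70) and 2.66% of F592A cells (interval 2.33 to 3.03), a ratio of 0.370 (interval 0.320 to 0.428). Cluster 13, led by mitotic genes such as Ube2c, Cenpf and Top2a, held 3.65% (interval 3.31 to 4.01) and 1.73% (interval 1.46 to 2.03), a ratio of 0.474 (interval 0.393 to 0.571). Cluster 8, led by C3, Cxcl14 and Pi16, was larger in F592A at 7.28% and 10.3%, a ratio of 1.42 (interval 1.29 to 1.55). The tenocyte-like cluster 3, with Kera, Tnmd and Fmod among its leading genes, held 12.1% and 13.4%, a ratio of 1.11 (interval 1.03 to 1.196). Cluster 14, with Angptl7, Prg4 and Kera, held 3.90% and 4.06%, and cluster 16, with Penk, Ptn and Mdk, held 9.75% and 8.28%, a ratio of 0.849 (interval 0.776 to 0.930). Cluster 18, led by Gdf10, Hmcn2 and Eln, had 101 WT and 453 F592A cells, and its leading genes differed between the libraries inside the cluster by a median of 0.50 on the log2 scale, so its size was not compared. Cluster 20, led by the interferon-induced genes Ifit1, Ifit3 and Isg15, had 73 WT cells and 1 F592A cell and was likewise not compared. A cluster mostly from 1 library, as were clusters 5, 18, 20 and the mural cluster 21 (31 WT and 99 F592A cells), may be a trait of that library and not a cell type. At resolution 1.2 the cells of cluster 5 went mostly to 2 new clusters, with a ratio of 0.843 together. The new cluster that held 557 of them had a ratio of 0.623, and the other, which also took 287 cells of cluster 18, a ratio of 1.10.

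**Figure D1:**
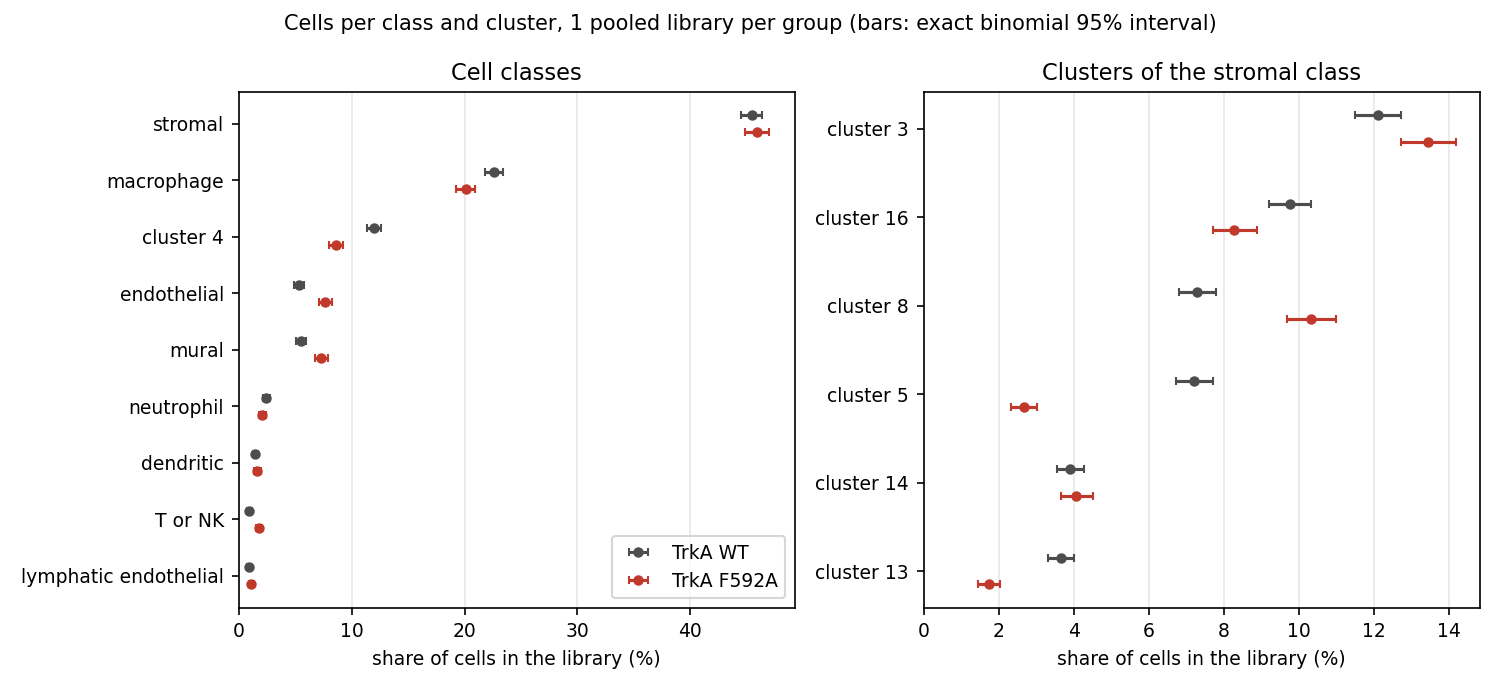
Share of cells in each library (percent) for the cell classes (left) and 6 numbered stromal clusters (right), with TrkA WT in grey and TrkA F592A in red and bars for the exact binomial 95% interval of 1 pooled library per group. The stromal points lie together at 45.4% and 45.9%, and cluster 5 lies at 7.20% in WT and 2.66% in F592A.

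The highest genes in F592A stromal cells included Gdf10, Penk and 2 metallothioneins, and most of the lowest were mitotic genes. Gdf10, a secreted member of the BMP family (ENSMUSG00000021943, GRCm38 chromosome 14, 33923587 to 33937983, plus strand), was 5.27 CPM in WT (interval 4.86 to 5.70) and 32.4 CPM in F592A (interval 31.3 to 33.6), a log2 ratio of 2.62 (interval 2.499 to 2.75). Next came Hmcn2, a hemicentin of the extracellular matrix, at 7.47 and 26.1 CPM (log2 ratio 1.80), and Penk, the precursor of enkephalin opioid peptides, at 17.4 and 47.7 CPM (log2 ratio 1.45). The metal-binding Mt2 and Mt1 had log2 ratios of 1.28 and 1.27, with Mt1 at 622 CPM in WT and 1502 CPM in F592A. Gpc3, a cell-surface heparan sulfate proteoglycan, had a log2 ratio of 1.26, and the transporter Abca8a one of 1.14. Lars2, the mitochondrial leucyl-tRNA synthetase, had a log2 ratio of 1.14 at 639 and 1406 CPM. The stress chaperones Hspa1b and Hspa1a had log2 ratios of 1.13 and 1.12. These copies are nearly identical, so how their UMIs were divided between them is uncertain. On the other side stood Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (ENSMUSG00000001403, chromosome 2, 164769898 to 164778822), at 67.2 and 21.8 CPM (log2 ratio -1.63, interval -1.70 to -1.56). Ccnb2, Cdca3, Cdk1, Birc5, Ccnb1, Cdkn3 and Cenpa, all genes of the cell cycle, had log2 ratios from -1.45 to -1.19. Igfbp2, which binds insulin-like growth factors, was 24.2 and 8.36 CPM (log2 ratio -1.53), and Il1rl1, the receptor for interleukin-33, was 46.6 and 20.5 CPM (log2 ratio -1.18).

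By size alone, 20 genes were at least 2-fold higher and 32 at least 2-fold lower in F592A stromal cells, of 5514 genes with at least 20 CPM in the higher library. With TMM factors that split was 28 and 24, and with median-of-ratios factors 27 and 24. Without cluster 13 only 11 genes were at least 2-fold lower. The stromal class mixed clusters in different proportions, clusters 5 and 13 mostly from WT and cluster 18 mostly from F592A. Gdf10, Hmcn2, Gpc3 and Abca8a are among the leading genes of cluster 18. With clusters weighted equally the log2 ratio of Gdf10 was 1.03, that of Hmcn2 0.85, that of Abca8a 0.36 and that of Hspa1a 0.69. That of Ube2c was -0.60, and those of the 7 other cell cycle genes named lay between -0.46 (Ccnb2) and -0.24 (Cenpa). Equal weighting averages CPM over clusters, so each value leans towards the cluster where the gene is highest and is not free of the mixture. For Gdf10, Hmcn2 and Abca8a that is cluster 18 (0.86, 0.96 and 0.47 inside it), and for the mitotic genes cluster 13. Without clusters 5 and 18 the log2 ratio of Gdf10 was 1.89, that of Hmcn2 0.79, that of Gpc3 0.71, that of Abca8a 0.64 and that of Il1rl1 -0.67. Without cluster 13 that of Ccnb1 was -0.05, and in cluster 3 alone those of Penk and Il1rl1 were -0.63 and 0.24.

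Gene lists fixed beforehand were compared by the median log2 ratio of their measured members minus the median of all measured genes of the class, which was -0.10 in stromal cells, while values beside gene names are plain log2 ratios. Of 32 lists, 11 lay in the top 2.5% and 6 in the bottom 2.5% of random lists matched on expression. The cell cycle list was the lowest at -0.92, with 35 of 40 members at least 1.5-fold lower and 0 of 40 above the class median, Stmn1 among them at -1.35. Without cluster 13 its median was -0.50, with clusters weighted equally it was -0.03, and in cluster 3 alone it was -0.09. The equally weighted value averages CPM over clusters and so mostly follows cluster 13, where Ube2c was 502 CPM against 9.27 CPM in other cells. Inside clusters 8 (-0.55), 16 (-0.40) and 5 (-0.37) the cell cycle list lay below every random list. Inside clusters 13 (-0.05), 14 (0.21) and 18 (0.08) it lay within their range. Transcripts of macrophages read in stromal cells were also lower. The phagocyte and complement list was at -0.87 (C1qa -1.32, C1qb -1.25, Fcgr3 -1.29) and the list of resident and alternatively activated macrophages at -0.48 (Pf4 -1.43), with C1qa at only 19.8 CPM in WT and 7.97 CPM in F592A stromal cells. With cells thinned to 2000 UMIs the resident macrophage list was at -0.06, inside the range of random lists. The haemoglobin list, which reads red blood cells, was at -0.62, with Hbb-bs at 32.2 and 16.9 CPM, but at 0.33 without clusters 5 and 18 and at 2.33 in cluster 3 alone. The hypoxia and glycolysis list was at -0.31, with 21 of 26 members not above the class median, including Ankrd37 (-1.41) and Gapdh (-0.66), against Hk2 at 0.82. The interferon response list was at -0.26 (Ifit1 -2.52, Isg15 -2.14, Ifit3 -1.76), and without cluster 20 it was at -0.06, inside the range of random lists. Inside clusters 5 (-0.31), 13 (-0.37) and 14 (-0.27) it lay in the bottom 2.5% of random lists. Inside clusters 3 (-0.13), 8 (-0.03), 16 (-0.02) and 18 (-0.19) it lay within their range.

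Lists that lay high in stromal cells covered developmental signals, stress genes and matrix. The leukocyte adhesion list was at 0.36 (7 measured, Icam1 0.50) and the Hedgehog list at 0.33, with 9 of 10 members above the class median and the target gene Gli1 at 1.19. The list of immediate early and dissociation genes was at 0.30, with 21 of 25 members above the class median (Socs3 0.60, Nr4a1 0.44). Tendon differentiation was at 0.29, with 15 of 20 members above the class median (Chodl 0.63, Ogn 0.52, Kera 0.37) and the sheath gene Tppp3 at -1.06. In the tenocyte-like cluster 3 alone this list was at 0.04, inside the range of random lists. The MHC class II list, mainly expressed by macrophages and dendritic cells, was at 0.26 (6 measured, Cd74 20.8 and 24.2 CPM), the BMP and GDF list at 0.21 (Id4 0.97, Id2 0.59), the Wnt list at 0.16 (Wnt2 -1.25, Rspo3 0.87, Sfrp4 0.76) and axon guidance at 0.15 (Sema3d 0.77). Oxidative phosphorylation was at 0.15 with 26 of 40 members above the class median (Atp5k 0.79, Ndufa3 0.78, Cox7c 0.63). The list of TGF-beta ligands, receptors and Smads was at 0.12, with 13 of 18 members above the class median and 0 at least 1.5-fold apart (Ltbp4 0.47, Tgfb3 0.36). Collagens and fibrous matrix were at 0.10, with 20 of 29 members above the class median, the basement membrane chains Col4a2 and Col4a1 at 0.70 and 0.51, Eln at 0.62 and Col5a3 at -0.75. With cells thinned to 2000 UMIs the TGF-beta (0.13), collagen (0.08), MHC class II (0.07) and leukocyte adhesion (0.14) lists lay inside the range of random lists, as did Hedgehog with clusters weighted equally (0.08). In cluster 3 alone collagens (0.00), BMP and GDF (0.04), Wnt (0.02), Hedgehog (0.13) and TGF-beta (0.08) lay inside the range of random lists and MHC class II was at -0.20, and with doublets kept MHC class II was at -0.0562.

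The other 15 lists lay inside the range of random lists in stromal cells. They were osteogenic (0.16), endothelial identity and sprouting (0.13), chondrogenic (0.13, Col2a1 0.63), angiogenic factors (0.13, Adm 0.84, Hgf 0.76), neurotrophins and receptors (0.11), IGF, FGF and PDGF (0.10, Fgf10 1.92 from 77 and 238 UMIs), sex-linked genes (0.08) and matrix proteases and inhibitors (0.07, Mmp13 0.69). The TGF-beta response list was at 0.01 (Igfbp3 0.57, Ccn2 -0.30), collagen processing at -0.06 (P4ha2 -0.69), lipid-associated macrophages at -0.06, inflammatory cytokines and chemokines at -0.10, neuropeptide receptors at -0.12, senescence and p53 at -0.12 (Cdkn2a -1.61) and myofibroblast contractile genes at -0.15. Members of some of these went both ways. Among 31 cytokine and chemokine genes 7 were at least 1.5-fold higher, such as Ccl5 (2.79), Il6 (1.83) and the eosinophil attractant Ccl11 (1.64), and 10 at least 1.5-fold lower, such as Tnf (-1.88). Free RNA of other cell types was not separated from these values. Il6 is a leading gene of cluster 18 (1.62 inside it), and inside other clusters it went from 1.57 in cluster 3 and 1.14 in cluster 8 to 0.03 in cluster 16 and -0.38 in cluster 13. Of 15 contractile genes 5 were at least 1.5-fold lower, with Cnn1 at -2.04, the smooth muscle actin Acta2 at -0.91 (572 and 305 CPM), Tpm2 at -0.79 and Tagln at -0.73. Phex, a bone mineralisation gene on the osteogenic list, had 17 WT and 151 F592A UMIs.

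Fewer stromal cells of the F592A library carried cell cycle RNA. With every cell thinned to 2000 UMIs, 16.3% of WT stromal cells (interval 15.3 to 17.4) and 9.70% of F592A stromal cells (interval 8.79 to 10.7) had at least 2 UMIs on the cell cycle list, a ratio of 0.594 (interval 0.530 to 0.667). The shares were 23.0% and 17.04% in endothelial cells, a ratio of 0.742 (interval 0.589 to 0.935), and 25.1% and 19.2% in mural cells, a ratio of 0.767 (interval 0.620 to 0.95002). In macrophages they were 17.1% and 15.1%, with a ratio interval from 0.764 to 1.02, and in cluster 4 they were 7.43% and 7.45%. Neutrophil cluster 6, taken as background, had shares of 9.90% (interval 6.15 to 14.9) and 8.66% (interval 4.40 to 14.97) at median depths of 2500 and 3018 UMIs, against 21344 and 23589 UMIs in stromal cells. Both cluster 4 shares were below it and are read as background. The F592A stromal share lay within its interval at this depth. Thinned to 1000 UMIs that share was 5.45% (interval 4.75 to 6.21), against 0.730% in F592A cells of cluster 6 (1 of 137, interval 0.0185 to 3.9997). WT cells of cluster 6 had 2.87% at that depth (7 of 244, interval 1.16 to 5.82), an interval that includes the F592A stromal share. Summed over the list, stromal cells had 1079 CPM in WT and 551 CPM in F592A, endothelial cells 985 and 633 CPM, mural cells 1485 and 926 CPM, macrophages 407 and 344 CPM, and 223 and 209 CPM were found in neutrophil cluster 6. Unthinned shares were 85.7% and 81.3% in stromal cells, 72.8% and 78.1% in endothelial cells, 77.9% and 82.3% in mural cells, 74.5% and 78.9% in macrophages, and 15.98% and 13.1% in neutrophil cluster 6. Thinning left out 42 WT and 19 F592A stromal cells and 42 and 10 cells of neutrophil cluster 6 as too shallow.

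Macrophages of the F592A library had more RNA of genes of alternative activation and, over the class as a whole, of MHC class II, and less of lipid-associated, interferon-induced and glycolytic genes. Retnla, a secreted protein of alternatively activated macrophages (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand), was 16.9 CPM in WT (interval 15.4 to 18.5) and 164 CPM in F592A (interval 158 to 169), a 9.69-fold difference (log2 ratio 3.28, interval 3.14 to 3.42). Ear2, an eosinophil-associated ribonuclease with close paralogs, had a log2 ratio of 1.60 (interval 1.37 to 1.84). The proton-sensing receptor Gpr65 was at 1.26, the lectin Clec10a at 1.23 and the prostaglandin-degrading enzyme Hpgd at 1.204. Arg1, which degrades arginine, went the other way at 37.7 and 14.5 CPM (log2 ratio -1.38, interval -1.56 to -1.20), and its log2 ratio was -0.45 as a per-cell mean. Rgcc, a cell cycle regulator that responds to complement, was 236 and 98.5 CPM (log2 ratio -1.26). The sheath gene Tppp3 and the protease Ctsk were at -1.12 and -1.01, and Fbxo32, a ubiquitin ligase, was 39.4 and 19.6 CPM. In WT the macrophage levels of Tppp3 and Ctsk were 0.43 and 0.26 of those in the highest class (mural cells and cluster 4). Free RNA of other cells was not separated from a macrophage difference in these 2 genes. By size, 11 genes were at least 2-fold higher and 8 at least 2-fold lower, of 4975, and that split was 17 and 6 with TMM factors and 17 and 5 with median-of-ratios factors.

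Of 30 lists in macrophages, 5 lay in the top 2.5% and 6 in the bottom 2.5% of random lists, relative to a class median of -0.07. The MHC class II list was at 0.46 with 8 of 8 members above the class median (Cd74 0.41, H2-Aa 0.40), but inside cluster 9, which these genes lead, Cd74 was at 0.09, H2-Aa at 0.06 and H2-DMa at -0.28, and the resident and alternatively activated list was at 0.32 with 16 of 18 members above it (Ccl8 717 and 1486 CPM). Axon guidance was at 0.32 (6 measured), oxidative phosphorylation at 0.22 and immediate early and dissociation genes at 0.15 (Hspa1b 0.99). The haemoglobin list was at -0.81, with Hbb-bs at 43.7 and 18.2 CPM, but at 0.0685 with clusters weighted equally. Below the range lay also the cell cycle list at -0.32, interferon response at -0.31 (Ifit2 -1.84, Ifit3 -1.80, 26 of 29 members not above the class median), collagen processing at -0.19 and hypoxia and glycolysis at -0.18. The lipid-associated list was at -0.27, with 12 of 16 members not above the class median. On it, the secreted phosphoprotein Spp1 was 2878 and 1454 CPM (log2 ratio -0.99), Cd9 was at -0.87, the lipid carrier Fabp5 at -0.80 and the protease Ctsl at -0.74. Cluster 17, led by Mmp12, Gpnmb and Spp1, held 2.60% of WT and 1.69% of F592A cells, a ratio of 0.651 that was 1.07 with components centred per library, and 86 of its 436 cells had barcodes that occurred in both libraries. With clusters weighted equally the lipid-associated list was at -0.10, inside the range of random lists, as were the cell cycle list in thinned cells (-0.07) and axon guidance (0.15) and collagen processing (-0.03) over every barcode.

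Endothelial cells of the F592A library had more RNA of interferon-induced genes and of Cxcl12, and less of cell cycle genes. RNA of matrix genes and of the list of inflammatory cytokines and chemokines read in them was also lower. It was not separated from free RNA of other cells. Cxcl12, a chemokine that guides leukocytes and progenitors, was 296 and 734.5 CPM (log2 ratio 1.31, interval 1.24 to 1.38), and the interferon-induced chemokine Cxcl10 was 23.6 and 67.5 CPM (log2 ratio 1.52, interval 1.28 to 1.76). Clic5, a chloride channel protein, had a log2 ratio of 1.88 (interval 1.57 to 2.20), the kinase scaffold Akap12 one of 1.34 and the ephrin receptor Epha4 one of 1.25. On the other side, the mitotic genes Ccnb2 and Cenpe were at -1.43 (interval -1.85 to -1.03) and -1.28, Nox4, an oxidase that makes hydrogen peroxide, at -1.41, and Prnd, the prion-like protein doppel, at -1.33. By size, 16 genes were at least 2-fold higher and 71 at least 2-fold lower, of 5806. That split was 29 and 41 with TMM factors and 30 and 40 with median-of-ratios factors, which moved the median of all measured genes from -0.09 to 0.02 and 0.03. List medians are given relative to the class median.

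Of 31 lists in endothelial cells, 1 lay in the top 2.5% and 9 in the bottom 2.5% of random lists. Interferon response was at 0.19 with 20 of 27 members above the class median (Iigp1 1.19, Ifi47 0.76, Irf1 0.66). The cell cycle list was at -0.61 with 20 of 34 members at least 1.5-fold lower (Hmmr -1.52, Birc5 -1.35). Lists of matrix and connective tissue genes were low together. They were chondrogenic (-0.77, 9 measured), tendon differentiation (-0.70, Scx -1.91, Fmod -1.34, Lum -1.31), osteogenic (-0.60, 4 measured), proteases (-0.59), collagens (-0.56, Col6a1 -1.47, Postn -1.07) and collagen processing (-0.29). Many of these genes are mainly expressed by stromal cells, and the endothelial level of Fmod was only 100 CPM in WT and 39.4 CPM in F592A. Inflammatory genes were at -0.44 (Ccl5 -3.82 from 97 and 9 UMIs, Il1b -1.92) and MHC class II at -0.67 (4 measured), while Spp1, a macrophage transcript in these data, was 186 and 23.1 CPM. Ccl5 and Il1b are likewise leading genes of other cells, the T or NK cells (2468 CPM) and macrophage cluster 9 (6397 CPM). With doublets kept, the MHC class II list was at 0.21, and with cells thinned to 2000 UMIs the chondrogenic list was at 0.04, and proteases (-0.14), collagen processing (-0.18) and the osteogenic list (-0.36) lay inside the range of random lists. The list of endothelial identity and sprouting genes was at 0.08, inside the range of random lists, with 18 of 28 members above the class median.

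**Figure D2:**
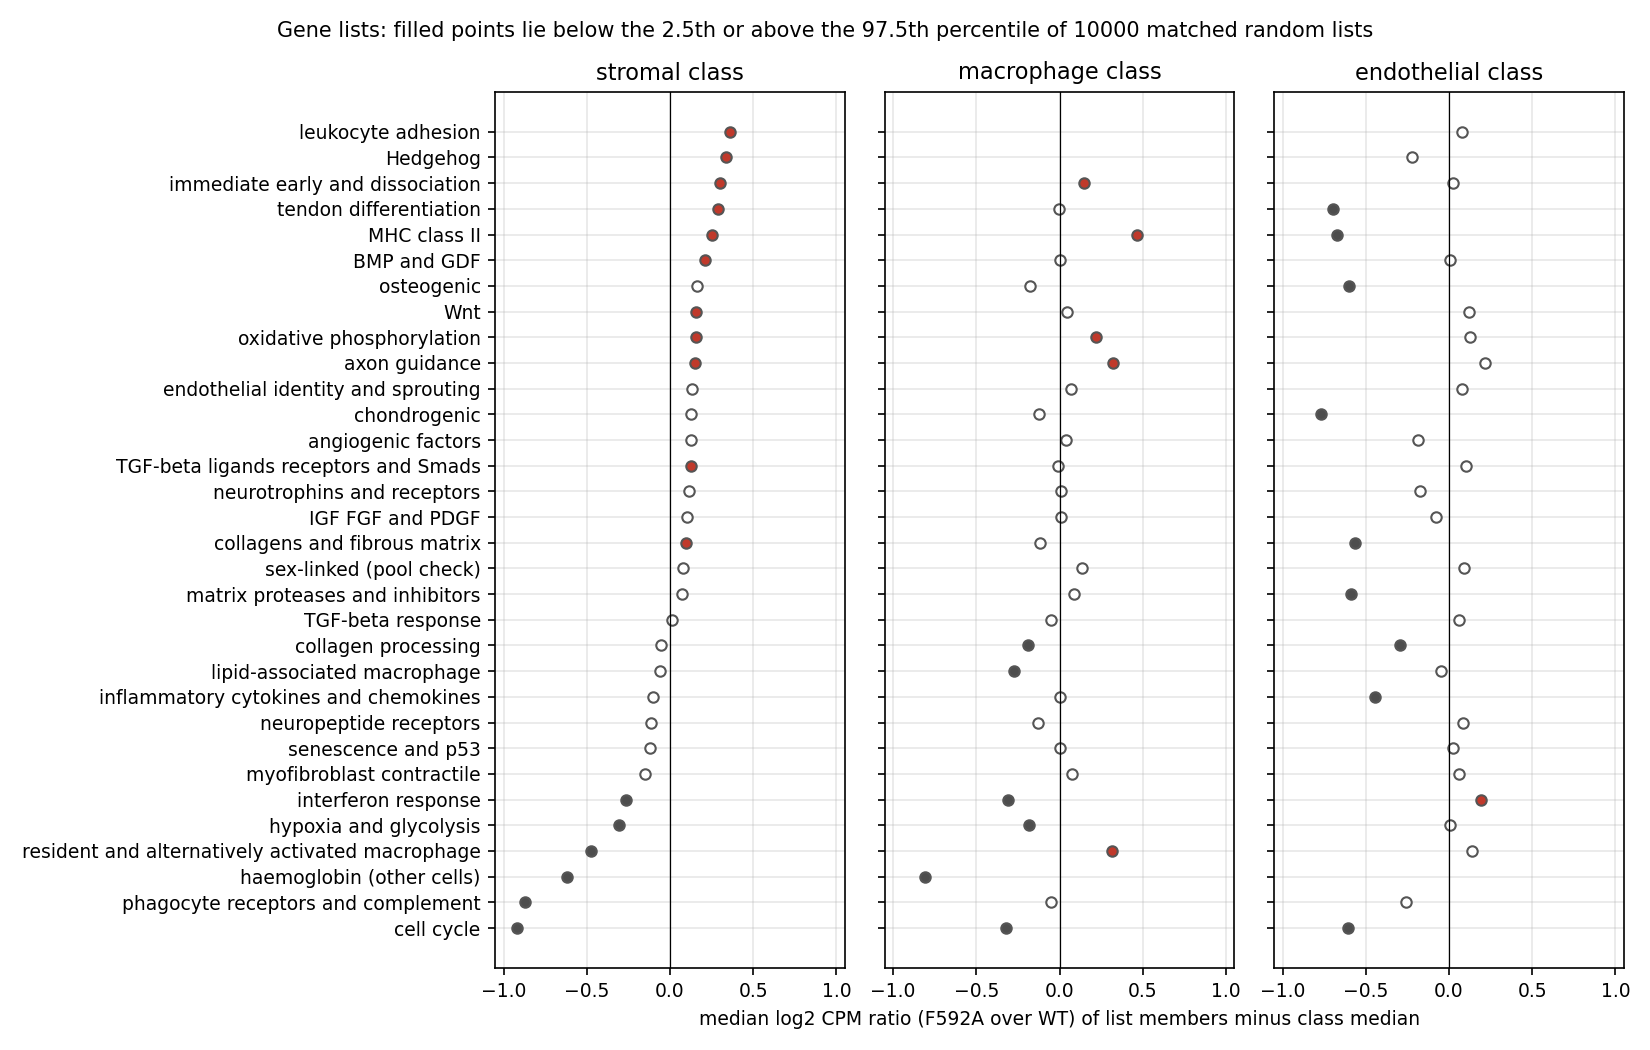
Median log2 CPM ratio (F592A over WT) of each gene list minus the class median, in stromal, macrophage and endothelial cells of 1 library per group, with filled points for lists in the top or bottom 2.5% of 10000 matched random lists and no bars, as there are no replicates. The cell cycle list lies at -0.92, -0.32 and -0.61 in the 3 classes, and tendon differentiation at 0.29 in stromal and -0.70 in endothelial cells.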

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

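Tests chosen only after the result was seen were those on dilution, surrounding tissue and cluster borders, on thinned depth and free RNA, and all 3 on shared barcodes. Several gene lists lay outside the range of random lists in opposite directions in different cell classes, and the difference between classes was not tested. The MHC class II list was at 0.26 in stromal cells and 0.46 in macrophages but at -0.67 in endothelial cells. With doublets kept the stromal and endothelial values turned to -0.0562 and 0.21. Collagens and fibrous matrix were at 0.10 in stromal cells and -0.56 in endothelial cells, and tendon differentiation was at 0.29 in stromal cells and -0.70 in endothelial cells. Interferon response was at -0.26 in stromal cells and -0.31 in macrophages but at 0.19 in endothelial cells. The resident and alternatively activated macrophage list was at -0.48 in stromal cells and 0.32 in macrophages. A signal outside the comparisons was that 715 barcodes occurred in both libraries with near-equal UMI totals.

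In the stromal class cluster 5 was smaller in F592A (ratio of shares 0.370), and more F592A cells were placed in cluster 18 (ratio of shares 5.98), which is no comparison of a cell type's size, as its leading genes differ between the libraries. The tables argue against the filter and doublet calls, as the ratios over all barcodes were 0.385 and 6.33, and against dilution by other tissue as the whole cause for cluster 5, as the tenocyte-like cluster 3 had a ratio of 1.11. With components centred per library, the cluster that held 632 cluster 5 cells had a ratio of 0.456. A further 219 and 171 of its cells went to clusters with ratios of 0.980 and 1.28. For cluster 5 this argues against splitting of the same cells by a shift common to all cells of a library. Centring removes only the mean of each library, so it cannot decide on splitting by a shift limited to some cell types. Open for cluster 5 stays also where its border is drawn. Its cells split at resolution 1.2 over clusters with ratios of 0.623 and 1.10 (0.843 together), the latter shared with cluster 18. For cluster 18 more surrounding tissue could have brought its cells along, as the endothelial ratio was 1.44. For cluster 18, real abundance and a shift in expression cannot be told apart, since centring sent 272 and 274 of its cells to 2 clusters of mostly other cells with ratios of 0.980 and 1.28, and an effect of TrkA inhibition was not tested apart from these.

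Cell cycle genes were lower in F592A stromal cells, with a list median of -0.92. The tables argue against depth per cell, which was higher in F592A, as the ratio of cycling shares at equal depth was 0.594, and against doublet calls and the filter, as the list median over all barcodes was also -0.92. They argue against free RNA that was higher in WT, as the list's summed CPM in neutrophil cluster 6 had a ratio of 0.941 (interval 0.721 to 1.22) against 1079 and 551 CPM in stromal cells. Open stays how much lies in the mixture of clusters. The value with clusters weighted equally (-0.03) cannot decide this, as it averages CPM over clusters and so mostly follows the mitotic cluster 13. The list median lay below every random list inside clusters 5 (-0.37), 8 (-0.55) and 16 (-0.40). Inside clusters 3 (-0.09), 13 (-0.05), 14 (0.21) and 18 (0.08) it lay within their range. A lower rate of division with TrkA blocked could give this pattern, but differences between the pools in the course of healing or in dissociation, which 1 library per group does not separate from genotype, stay open.

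Of 764 barcodes found in both libraries, 715 had near-equal UMI totals, with medians of 829 UMIs in WT and 759 UMIs in F592A. The tables argue against chance, as profiles of the same barcode correlated better than unmatched ones by 0.399. They also argue against reads moved between these 2 libraries, which would leave unequal totals, as the median of the smaller over the larger total was 0.907. A source outside both libraries likely gave reads to both. The female transcript Xist was 140-fold (WT, 15 UMIs, interval 69.8 to 270) and 170-fold (F592A, 16 UMIs, interval 83.5 to 339) higher per UMI in these barcodes than in the others. Hbb-bs was 236630 and 232516 CPM there. What this source was stays open and no biological explanation was tested, and 96 WT and 84 F592A barcodes of this kind passed as cells.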

How the results depend on the processing

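Apart from the main settings, 138 ratios of shares kept their direction and size, 19 moved and 1 reversed, and of the named genes' log2 ratios 322 kept both, 166 moved and 2 reversed. Of the list medians 698 stayed, 70 moved, 45 grew stronger, 48 weaker and 12 reversed. The stromal ratio of shares was 1.15 at resolution 0.4 and 0.966 with components centred, where cluster 5 was at 0.456 and cluster 17 at 1.07, against 0.651 in the main setting. Cluster 5 was at 0.843 at resolution 1.2, and macrophages were at 0.953 of immune cells. With no minimum CPM and at least 10 rather than 100 UMIs, 580 genes were at least 2-fold higher and 702 lower in stromal cells. Under that setting the counts were 321 and 478 in macrophages and 328 and 698 in endothelial cells. With at least 100 CPM the counts were 10 and 6, 5 and 3, and 4 and 16. Without cluster 13, 11 genes were lower in stromal cells. In macrophages 17 were higher and 4 lower over every barcode, 5 lower with doublets kept and 14 lower in thinned cells. TMM factors gave 17 higher in macrophages and 29 higher and 41 lower in endothelial cells, median-of-ratios factors gave 17 higher and 5 lower in macrophages and 30 higher and 40 lower in endothelial cells, and thinned endothelial cells had 19 lower. In cluster 3 alone Penk was at -0.63, Il1rl1 at 0.24, MHC class II at -0.20, leukocyte adhesion at -0.0154 and haemoglobin at 2.33, and 4 lists lay in the top 2.5%. Without clusters 5 and 18 stromal haemoglobin was at 0.33, and with clusters weighted equally macrophage haemoglobin was at 0.0685 and 3 macrophage lists lay in the bottom 2.5%. MHC class II was at -0.0599 in stromal and 0.21 in endothelial cells over every barcode, and at -0.0562 and 0.21 with doublets kept. In endothelial cells it was at 0.0450 in thinned cells and 0.0251 as a per-cell mean, and the chondrogenic list was at 0.0383 in thinned cells. There, 3 lists lay in the top 2.5% over every barcode, and 2 with doublets kept, in thinned cells and as a per-cell mean. The ratio of cycling shares was 0.948 unthinned, 0.487 with at least 3 UMIs and 0.502 thinned to 1000 UMIs in stromal cells, 1.06 unthinned in macrophages, and 1.07 unthinned and 0.480 thinned to 1000 UMIs in endothelial cells. The cause was not tested, except that unthinned shares rise with depth and looser minima admit more genes by construction. Equal weighting has no endothelial value, as that class is 1 cluster, and cluster 18 has no value at resolutions 0.4 and 1.2 or with centring, as no cluster was led by its cells. No paired analysis was possible because each group is 1 pooled library.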

Other observations

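All values within clusters were chosen only after the class values were seen. Contractile genes were lowest relative to WT in cluster 16, a stromal cluster marked by Ptn, Mdk and Postn. In it, Acta2, the smooth muscle actin of myofibroblasts, was 803.5 CPM in WT and 197 CPM in F592A (log2 ratio -2.03), and Cnn1, a calponin that binds actin, had 393 and 32 UMIs (log2 ratio -3.13). The contractile list was at -0.42 there, below every random list, with 7 of 15 members at least 1.5-fold lower, against -0.22 in cluster 18, -0.13 in cluster 8, -0.00 in cluster 3 and 0.16 in the cycling cluster 13, and the difference between clusters was not tested. Cnn1 was also lower in clusters 3 (-0.80), 4 (-1.52) and 13 (-1.30). The list of inflammatory cytokines and chemokines was also low in cluster 16 at -0.74, with 17 of 26 members at least 1.5-fold lower. It lay in the bottom 2.5% of random lists also in clusters 3 (-0.31), 4 (-0.45), 5 (-0.15), 13 (-0.35) and 14 (-0.24). In cluster 8 it was at -0.14, inside the range of random lists. In cluster 18 it was high at 0.56, with 17 of 18 members above the cluster's median. Its members Il1b and Ccl4 are leading genes of macrophage clusters 9 and 0. The phagocyte and complement list was also low in clusters 16 (-0.72), 3 (-0.82), 4 (-0.80), 13 (-0.35), 14 (-0.59) and 8 (-0.76), and inside the range of random lists in cluster 5 (-0.20). Free RNA of macrophages was not separated from a stromal difference in the cytokine list. Tendon differentiation was at 0.39 in cluster 16 and 0.19 in cluster 14, each in the top 2.5% of random lists, and the BMP and GDF list was at 0.31 in cluster 8. The chemokine Ccl5 was higher in cluster 3 (86 and 689 UMIs, log2 ratio 3.01), cluster 13 (6 and 169 UMIs), cluster 16 (log2 ratio 4.41), cluster 4 (log2 ratio 3.97), cluster 8 (log2 ratio 1.76) and cluster 5 (log2 ratio 1.04), and clusters 14 and 18 had at most 9 UMIs per library. Ccl5 leads the T or NK cells, at 2468 CPM, whose share was 1.89 times that in WT, and its RNA in stromal cells was not separated from theirs.

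Some differences were shared by clusters 3, 4, 5, 8, 13, 14, 16 and 18, those with enough cells. Tppp3, a gene of tendon sheath cells, was lower in all 8, with log2 ratios from -0.32 in cluster 18 to -1.80 in cluster 13. Igfbp2 had intervals below 0 in 6 of the 8, down to -2.15 in cluster 13, and intervals that included 0 in clusters 5 (-0.28) and 14 (-0.80). The metallothionein Mt1 was higher in all 8, from 0.67 in cluster 3 to 1.66 in cluster 18, and Lars2 was higher in all 8, from 0.80 to 1.09. Oxidative phosphorylation was higher in all 8, from 0.16 in cluster 5 to 0.27 in cluster 14. MHC class II genes were at 1.32 in cluster 5, 0.89 in cluster 13 and 0.92 in cluster 14, but at -0.44 in cluster 4. Their UMIs there were not separated from free RNA, as H2-Ab1 was 22.8 CPM in cluster 13 and 10.3 CPM in cluster 5, against 6607 CPM in the macrophage cluster 9. Glycolytic and hypoxia genes were at -0.38 in cluster 3, -0.30 in cluster 4 and -0.33 in cluster 14. The enkephalin precursor Penk was higher in clusters 5 (1.12), 8 (1.54), 13 (1.58) and 16 (1.80, where it is a leading gene) and lower in clusters 3 (-0.63) and 4 (-0.27), and Phex had 1 WT and 112 F592A UMIs in cluster 18.

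In cluster 4, the haemoglobin list was at -4.86, with Hbb-bs at 68.4 CPM in WT and 2.58 CPM in F592A, while mural cells had 54.5 and 267 CPM. The male gene Ddx3y was 73.7 and 73.6 CPM over all cells and Xist 0.0681 and 0.0763 CPM, values of male pools. Barcodes found in both libraries made up 86 of 436 cells in cluster 17 and 37 of 70 cells in cluster 7. In those barcodes the acute phase gene Saa3 was 6053 and 5868 CPM, the liver and choroid plexus gene Ttr 2076 and 2030 CPM, and Arg1 330 and 275 CPM. With these barcodes left out the macrophage log2 ratio of Arg1 was -1.61.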
